A study of Drosophila melanogaster with 6 samples.

How the data were processed

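Total RNA from the central brain of Drosophila melanogaster pupae was measured on 6 Agilent single-colour (Cy3) arrays. Per the labels, the tissue was taken 24 h after puparium formation at 25 °C, and the RNA was isolated with an RNeasy kit and labelled with a low-input kit. In 3 control arrays the flies carried the mushroom body driver OK107-Gal4 and UAS-dicer2. In 3 knockdown arrays they also carried a UAS-DIP2-RNAi transgene. Replicate 1 of both groups was hybridised on 1 slide, and replicates 2 and 3 of both groups on another slide.

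The deposited scanner files, written by Agilent Feature Extraction 10.5.1.1 under protocol GE1_105_Dec08, give an intensity for each spot. The processed intensity had the background and a spatial trend subtracted within the array, a multiplicative trend removed and surrogate values set for dim spots, per the file headers. It was not normalised between arrays. The deposited files also give the mean signal, the median local background and quality flags of each spot. The authors' value table is on a log2 scale normalised between arrays by a method not given in the sources used here. Its column medians were 8.71 for control replicate 1, 8.71 for control replicate 2, 8.71 for control replicate 3, 8.71 for knockdown replicate 1, 8.71 for knockdown replicate 2 and 8.71 for knockdown replicate 3. The log base was read from how the values follow the scanner intensities, and the centring and the treatment of dim spots stay unknown, so the table served as an alternative only.

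The processed intensities were used as log2 values minus the 75th percentile of their array. Control spots and spots marked as outliers were left out, replicate spots of a probe were averaged, and the 97 probes that lacked a value on some array were dropped. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which held for 19344 of 32162 probes. The 75th percentile of the processed intensity was 1385 in control replicate 1, 577 in control replicate 2, 399 in control replicate 3, 466 in knockdown replicate 1, 515 in knockdown replicate 2 and 466 in knockdown replicate 3. Between 62.4% and 66.9% of spots were well above background on an array, and 0 spots were saturated. The number of arrays limits the precision of every value.

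Probes were matched to genes through RefSeq transcripts (17757 probes), otherwise through a current or older CG number (2574 probes). A further 9 probes kept the name in the scanner files. Probes that matched several genes (227), that gave conflicting matches (25) or that had no gene name (11570) were not used for genes. This named 12956 genes, and 14270 of the kept probes were named. Gene names follow the Release 6 annotation. Positions are those of the probes on the older build dm3 given in the files. The array also carries the name Dip2 for a different gene, so DIP2 was taken by its identifier CG7020. The kept probe with the highest mean level stood for its gene, which gave 9081 genes.

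Genes were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes and Benjamini-Hochberg adjustment over all genes, with an adjusted p threshold of 0.05. A looser count took genes with at least a 2-fold change and an unadjusted p under 0.05. DIP2 and gkt were also compared by exact two-sided permutation tests, whose smallest possible p is 0.1. Of 27 gene lists with 943 entries, 24 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01. camera with an estimated correlation and fry stood beside it. The tests, the lists and the rule for named genes were fixed before the data were examined. By that rule DIP2 and gkt are always named. In each direction up to 12 genes past the threshold with non-overlapping groups are named, filled up to 6 by the smallest p. From each list up to 4 members with the smallest p are named, and up to 12 from a list past the threshold. The comparison without knockdown replicate 2 was among the alternatives fixed at the start. The 5 largest changes in each direction without that array, and any gene said to be so, were chosen after their values were seen.

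A gene below the detection level of every array of a group is given only a bound on its fold change. The bound replaces values under the dimmest well-above-background signal of an array, between -7.27 and -6.44 on the scaled log2 axis, by that signal, and none is given where no value lay under it. Simulated arrays with the residual spread of each gene were run through the same steps. At the 6-array size, 28% of genes changed 2-fold, 76% of genes changed 4-fold and 82% of genes changed 8-fold were recovered, with 2 false calls. Without knockdown replicate 2 these shares were 50%, 94% and 92%, with 5 false calls. Genes were independent in this simulation, so it does not test the list calls. It also gave all arrays of a gene the same spread. In the data knockdown replicate 2 deviated more, with an SD across genes of 1.08 against 0.29 to 0.41 in control arrays. The shares and false calls at the 6-array size may therefore not hold for the real arrays.

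The alternatives tried were another background correction (normexp with offset 50), 3 other scalings, stricter and no filters on dim probes, the mean of a gene's probes, every probe alone, a trended robust prior, array weights, the authors' value table, the replicate number or the slide as a block, and each array left out in turn. A fit to slide 2 alone and a repaired normexp correction were added after seeing the data. The plain normexp correction was dropped for single genes and lists once its fit was seen to fail on some arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for reading the files and drawing.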

Results

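Gene expression in the pupal central brain was profiled on 6 single-colour arrays, 3 from control flies and 3 from flies with RNA interference against DIP2 (disco-interacting protein 2). The transgenes were driven by OK107-Gal4, which is active in the Kenyon cells of the mushroom body, whereas the RNA came from the whole central brain. The series title names glaikit (gkt) and the bifurcation of mushroom body axons. The single comparison of the design, knockdown against control, therefore asks which transcripts differ when DIP2 is knocked down. Levels are log2 intensities relative to the 75th percentile of each array. Across genes, which are not independent replicates, knockdown replicate 2 had correlations of 0.905 to 0.916 with the other arrays. All other pairs of arrays had correlations of 0.978 to 0.992.

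The transcript of gkt, which encodes a tyrosyl-DNA phosphodiesterase, was 3.15-fold less abundant in the knockdown arrays, while DIP2 itself hardly differed. The level of gkt (CG8825, probe at 3163088 to 3163147 on 2L) was 2.90 ± 0.06 (SD, n = 3) in control and 1.24 ± 0.24 (SD, n = 3) in knockdown arrays. This is a difference of -1.66 (SE 0.16, 95% confidence interval -2.05 to -1.26), and all 3 knockdown arrays lay below all 3 control arrays. All 3 gkt probes were lower, by differences of -1.66, -1.75 and -2.15. The adjusted p over all genes was 0.0677 and missed the threshold, and the exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. Without knockdown replicate 2 the difference was -1.52 with an adjusted p of 0.00927, within a range of 0.000818 to 0.930 over the alternatives. With the slide as a block the difference was -1.66 (adjusted p 0.221). It was -1.56 between the single arrays of slide 1 and -1.70 within slide 2.

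DIP2 (CG7020, probe at 250328 to 250387 on 3L) had a level of 2.14 ± 0.29 (SD, n = 3) in control and 1.99 ± 0.20 (SD, n = 3) in knockdown arrays. The difference was -0.15 (SE 0.20, 95% confidence interval -0.64 to 0.33; adjusted p 0.852, exact permutation p 0.6), smaller than the spread between replicates. The other 3 DIP2 probes differed by -0.32, 0.24 and 0.14. The difference was -0.48 between the arrays of slide 1 and 0.01 within slide 2, and -0.15 with the slide as a block. It was 0.01 without control replicate 1, so no direction can be given for DIP2 in RNA from the whole central brain.

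**Figure D1:**
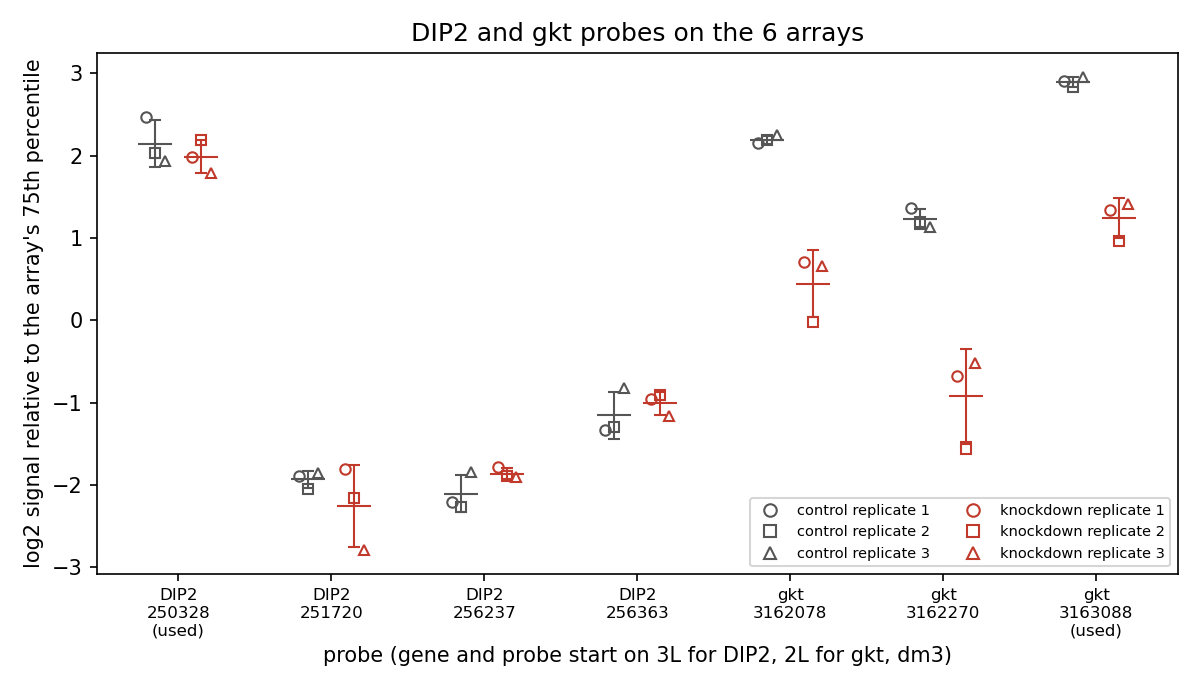
Log2 signal relative to the array's 75th percentile (vertical axis) for each kept probe of DIP2 and gkt (horizontal axis, with the probe's start on dm3). Points are single arrays, and bars are group means with SD (n = 3). The knockdown arrays lie below the control arrays at all 3 gkt probes and overlap with them at all 4 DIP2 probes.

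Over all 9081 genes, 4 passed the adjusted threshold, 1 higher and 3 lower in knockdown. P5CDh2, which encodes a pyrroline-5-carboxylate dehydrogenase of proline breakdown, was at least 4.78-fold lower (adjusted p 0.00926). TTLL15, of the tubulin tyrosine ligase-like family, was at least 7.81-fold lower (adjusted p 0.0236). Both were detected on all 3 control arrays and on 0 of 3 knockdown arrays. CG11052 fell from -1.97 ± 0.13 to -4.50 ± 0.34 (SD, n = 3 each), a difference of -2.53 (SE 0.20) or 5.76-fold (adjusted p 0.0372). CheB53a, of the CheB family of chemosensory proteins, was at least 3.02-fold higher (adjusted p 0.0293) and was detected on 0 of 3 control arrays. Their probes start at 17706252, 6642997 and 3834079 on 3R and at 12354965 on 2R. TTLL15, CG11052 and CheB53a had no second probe with a value on every array, so each of these calls rests on a single probe. A second probe of P5CDh2, starting at 17706341, was lower too, and its remaining probes were well above background on 0 arrays.

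The next genes by p missed the threshold, although their groups did not overlap. On the higher side were Dnaaf3, a dynein assembly factor, with a difference of 2.59 (SE 0.23, adjusted p 0.0563) and detection on 2 of 3 control arrays, the dynactin subunit gene DCTN5-p25 with 1.25 and an adjusted p of 0.0991, and dia, which encodes the formin diaphanous, with 1.05 and an adjusted p of 0.0991. CG2614 and CG8833 had differences of 1.11 and 1.15. A second probe of DCTN5-p25 differed by -0.01, and a second probe of CG2614 by 0.22. On the lower side were Pdh, the photoreceptor dehydrogenase gene, with -2.49 (SE 0.25, adjusted p 0.0677), detected on 2 of 3 knockdown arrays, and CG31955 with -2.20 (SE 0.23, adjusted p 0.0677).

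At an unadjusted limma p under 0.05, 486 genes or 5.35% differed, where chance gives 5% or 454. Of these, 110 differed at least 2-fold, 53 higher and 57 lower. Without knockdown replicate 2 the count at that p was 1051 genes or 11.6%, above the 5% that chance gives. The groups did not overlap for 1262 genes or 13.9%, where chance gives 10%. In each of the 4 called genes the groups did not overlap, and without knockdown replicate 2 all 4 were called among 43. Leaving out other arrays ended most of these calls. The count was 0 without control replicate 1, 2 without control replicate 2, 0 without control replicate 3, 1 without knockdown replicate 1 and 0 without knockdown replicate 3, where limma gave 285, 270, 528, 516 and 478 genes at unadjusted p under 0.05. With the slide as a block limma called 0 genes (489 at unadjusted p under 0.05), and the 4 genes had adjusted p values of 0.0967 to 0.107. Within slide 2 it called 0 (228 at unadjusted p under 0.05). Between the arrays of slide 1 and within slide 2, P5CDh2 was at least 5.05-fold and 4.66-fold lower, TTLL15 at least 7.41-fold and 8.02-fold lower, and CheB53a at least 4.22-fold and 2.56-fold higher. The differences for CG11052 were -2.84 and -2.37.

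**Figure D2:**
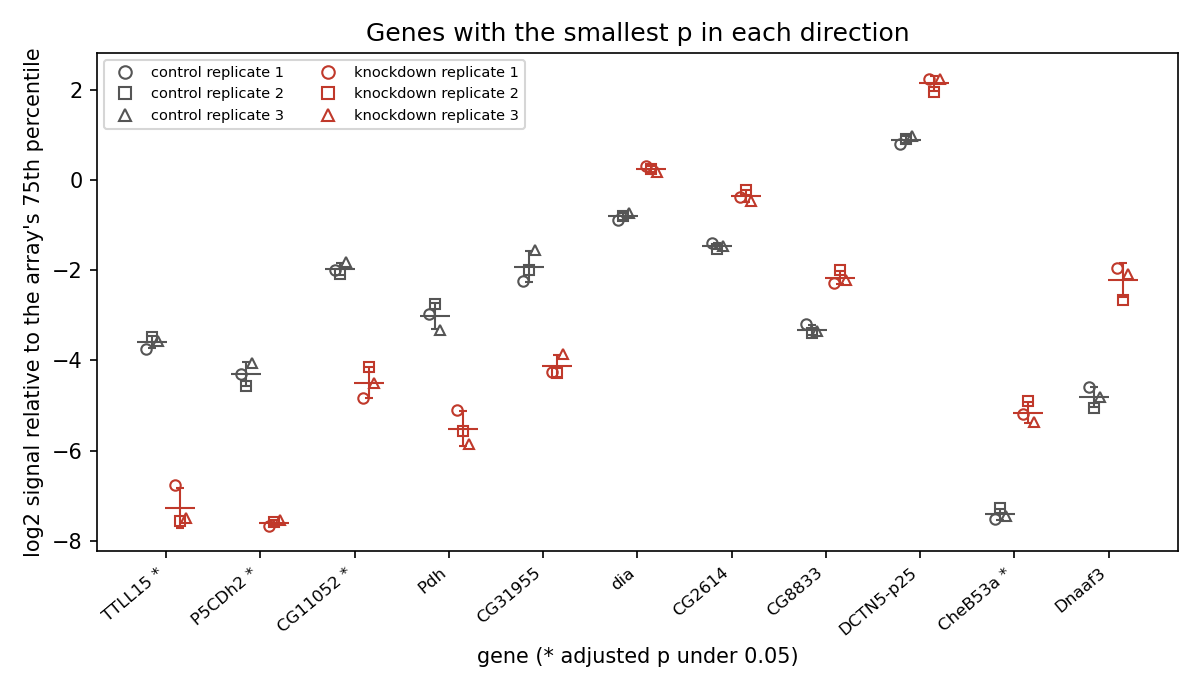
Log2 signal relative to the array's 75th percentile (vertical axis) of the genes with the smallest p in each direction besides gkt (horizontal axis). Points are single arrays, bars are group means with SD (n = 3), and a star marks the 4 genes with an adjusted p under 0.05. In each gene the 3 knockdown arrays lie on one side of the 3 control arrays.

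Without knockdown replicate 2, 43 genes passed the threshold, 24 higher and 19 lower in knockdown, and all 4 genes called with 6 arrays were among them. gkt fell by 1.52 on the log2 scale. The flavin monooxygenase gene Fmo-2 rose by 3.11 (SE 0.31, adjusted p 0.0298), Dnaaf3 by 2.81 (SE 0.16, adjusted p 0.00593) and CG33914 by 1.72 (SE 0.18, adjusted p 0.0339). Of 2 neighbouring methuselah-like receptor genes on 2R, mthl4 rose by 2.86 (SE 0.11, adjusted p 0.00385) and mthl3 was at least 5.45-fold lower (adjusted p 0.00524). mthl3 was detected on all 3 control arrays and on knockdown replicate 2, but on 0 of the 2 knockdown arrays compared here. CG33914 was detected on 2 of 3 control arrays. With all 6 arrays the differences were 2.14 for Fmo-2, 2.07 for mthl4 and -2.06 for mthl3. Knockdown replicate 2 lay within the range of the control arrays for Fmo-2, at -5.22, and for mthl3, at -3.95, and close to it for mthl4, at -3.50. The cytochrome P450 gene Cyp4d21, which was detected on 0 of 3 knockdown arrays, was at least 3.49-fold lower both with and without knockdown replicate 2. chp, which encodes the photoreceptor protein chaoptin, fell by 1.13 (adjusted p 0.0445).

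Of the 24 gene lists tested, 8 passed the threshold, 6 lower and 2 higher in knockdown. Neuron and synapse genes, Dpr and DIP cell surface proteins, Kenyon cell markers, muscle genes, optic lobe and photoreceptor genes and axon guidance genes were lower. Cytosolic ribosomal proteins and neuroblast and cell cycle genes were higher. In each of the 8 lists, 0 members passed the threshold over all genes. None of the 8 calls held with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, gave adjusted p values of 0.483 or more. In 6 of the 8 lists the shift was largest on knockdown replicate 2, as the plot of list medians shows; ribosomal proteins and axon guidance genes were the exceptions. Without that array 7 lists passed, 6 of them the same lists in the same direction, and 0 with an estimated correlation. Slide 2 holds knockdown replicate 2, so values within slide 2 and with the slide as a block are no separate support for the calls. Other splits of the 6 arrays into equal groups gave 5 to 9 lists each under the same test.

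Neuron and synapse genes had a median difference of -0.46, with 37 of 39 members below 0 (adjusted p 1.81e-08; adjusted p = 0.901 with an estimated correlation). The nicotinic receptor genes nAChRalpha6 and nAChRalpha3 differed by -0.73 (SE 0.16) and -0.74 (SE 0.18), the potassium channel gene Sh by -0.60 (SE 0.19) and the syntaxin gene Syx1A by -0.52 (SE 0.18). The acetylcholinesterase gene Ace was among the 2 members above 0, at 0.48 (SE 0.25) and at 0.22 without knockdown replicate 2. Adjusted over the list alone, 0 members passed. The median was -0.06, -0.96 and -0.17 on knockdown replicates 1, 2 and 3. It was -0.25 between the arrays of slide 1 and -0.56 within slide 2 (adjusted p 8.58e-08), and the call held with the slide as a block (adjusted p 7.63e-09) and without knockdown replicate 2 (median -0.12, adjusted p 0.00109).

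Kenyon cell markers had a median difference of -0.25, with 25 of 31 members below 0 (adjusted p 4.87e-05; adjusted p = 0.710 with an estimated correlation). rgn differed by -1.02 (SE 0.27), the dopamine receptor gene Dop1R1 by -0.60 (SE 0.17), the splicing factor gene mbl by -0.52 (SE 0.17), and dnc, the phosphodiesterase gene of olfactory memory, by -0.44 (SE 0.20). Adjusted over the list alone, 0 members passed. The median was -0.21 on slide 1 and -0.31 within slide 2 (adjusted p 0.000681), the call held with the slide as a block (adjusted p 3.66e-05), and without knockdown replicate 2 the median was -0.16 (adjusted p 0.00109) and dnc was at -0.29. Without control replicate 3 the median was also -0.16 (adjusted p 5.90e-05). Mushroom body neuron remodelling genes, by contrast, had a median of 0.00 (adjusted p 0.869), with the chemokine-like gene orion at 0.38 (SE 0.17) and the ecdysone receptor gene EcR at -0.75 (SE 0.35). These 3 values were -0.0080, 0.21 and -0.36 without knockdown replicate 2.

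Axon guidance and branching genes had a median difference of -0.04, with 41 of 68 members below 0 (adjusted p 0.0119; adjusted p = 0.901 with an estimated correlation). The teneurin gene Ten-a differed by -0.50 (SE 0.17), RhoGAPp190 by -0.34 (SE 0.13), the Wnt receptor gene drl by -0.35 (SE 0.16) and the microtubule-associated protein gene futsch by -1.22 (SE 0.58). drl was at -0.22 without control replicate 1, and futsch at -0.53 without knockdown replicate 2. Adjusted over the list alone, 0 members passed. The call held with the slide as a block (adjusted p 0.00677) but not within slide 2 (median -0.06, adjusted p 0.0995) or with array weights (median -0.05, adjusted p 0.0953). It was also lost without control replicate 1 (median -0.01, adjusted p 0.267) and without knockdown replicate 3 (median -0.0063, adjusted p 0.407), and the slide 1 median was -0.12. The median was -0.08 without control replicate 2, -0.07 without control replicate 3, -0.13 without knockdown replicate 1 and -0.07 without knockdown replicate 2. Dpr and DIP cell surface proteins, synaptic partner receptors that are unrelated to DIP2, had a median of -0.51 with 28 of 31 members below 0 (adjusted p 1.06e-05; adjusted p = 0.901 with an estimated correlation). DIP-alpha differed by -0.65 (SE 0.25) and dpr3 by -0.83 (SE 0.47), and 0 members passed adjusted over the list alone. The median was -0.10 on slide 1, -0.67 within slide 2 (adjusted p 3.58e-07) and -0.51 with the slide as a block (adjusted p 6.70e-06). Without knockdown replicate 2 the median was -0.04 and the call was lost (adjusted p 0.454), with DIP-alpha at -0.42 and dpr3 at -0.29. It was also lost with array weights (median -0.04, adjusted p 0.291).

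Optic lobe and photoreceptor genes had a median difference of -0.14, with 24 of 30 members below 0 (adjusted p 0.00671; adjusted p = 0.710 with an estimated correlation). chp differed by -1.39 (SE 0.26) and was the 1 member that passed adjusted over the list alone. Without knockdown replicate 2, 3 members passed adjusted over the list alone. Optix, an eye homeobox gene, differed by -0.77 (SE 0.20), and ato, the proneural gene atonal, was higher by 1.25 (SE 0.37). The median was -0.09 on slide 1, -0.18 within slide 2 (adjusted p 0.0141) and -0.07 without knockdown replicate 2 (adjusted p 0.0118), and the call held with the slide as a block (adjusted p 0.00677). It was -0.22 without control replicate 3 and -0.23 without knockdown replicate 1. The call was lost with the mean of a gene's probes (median -0.09, adjusted p 0.0661) and with the repaired normexp correction (median -0.015, adjusted p 0.0668). Muscle genes had a median of -0.37 with 21 of 27 members below 0 (adjusted p 0.000145; adjusted p = 0.710 with an estimated correlation). The giant spectrin-repeat protein gene Msp300 differed by -0.37 (SE 0.12), twi by -0.85 (SE 0.33), the titin-like gene sls by -0.63 (SE 0.25) and the actin gene Act87E by -1.97 (SE 1.13), and 0 members passed adjusted over the list alone. The median was -0.27 on slide 1, -0.49 within slide 2 (adjusted p 0.000640) and -0.23 without knockdown replicate 2 (adjusted p 0.00153), and the call held with the slide as a block (adjusted p 0.000250). twi was at -0.52, sls at -0.35 and Act87E at -0.59 without knockdown replicate 2. The muscle median was -0.09 in the authors' value table and -0.13 with the repaired normexp correction, and the call held in both (adjusted p 0.000669 and 0.00579).

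Cytosolic ribosomal proteins had a median difference of 0.22, with 75 of 79 members above 0 (adjusted p 9.19e-07; adjusted p = 0.901 with an estimated correlation), but the call was lost after quantile normalisation (median -0.02, adjusted p 0.429) and in the authors' value table (median -0.05, adjusted p 0.220). RpS20 differed by 0.31 (SE 0.12), RpL9 by 0.52 (SE 0.21) and RpS21 by -0.50 (SE 0.18), and 0 members passed adjusted over the list alone. The median was 0.43 on slide 1, 0.11 within slide 2 (adjusted p 0.0145) and 0.22 with the slide as a block (adjusted p 2.67e-08), and it was 0.05 without control replicate 1, where the call was lost (adjusted p 0.118) and RpL9 was at 0.30. Neuroblast and cell cycle genes had a median of 0.38 with 40 of 43 members above 0 (adjusted p 0.0117; adjusted p = 0.967 with an estimated correlation). The kinase gene aurB differed by 0.83 (SE 0.41), and the neuroblast genes wor and ase by 1.32 (SE 1.13) and 1.30 (SE 1.13). Adjusted over the list alone, 0 members passed. This median came from knockdown replicate 2, at 1.42 against -0.12 and -0.15 on the other knockdown arrays. Without that array the list was lower in knockdown (median -0.13, adjusted p 0.00109), with aurB at 0.40, wor at -0.057 and ase at -0.064. That lower call was lost with an estimated correlation (adjusted p 0.707) and with fry (adjusted p 0.469). With array weights the median was -0.06 (adjusted p 0.225). The median was 0.62 without knockdown replicate 1 and 0.62 without knockdown replicate 3. The median was -0.10 on slide 1, 0.63 within slide 2 (adjusted p 2.27e-05) and 0.38 with the slide as a block (adjusted p 0.0131).

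**Figure D3:**
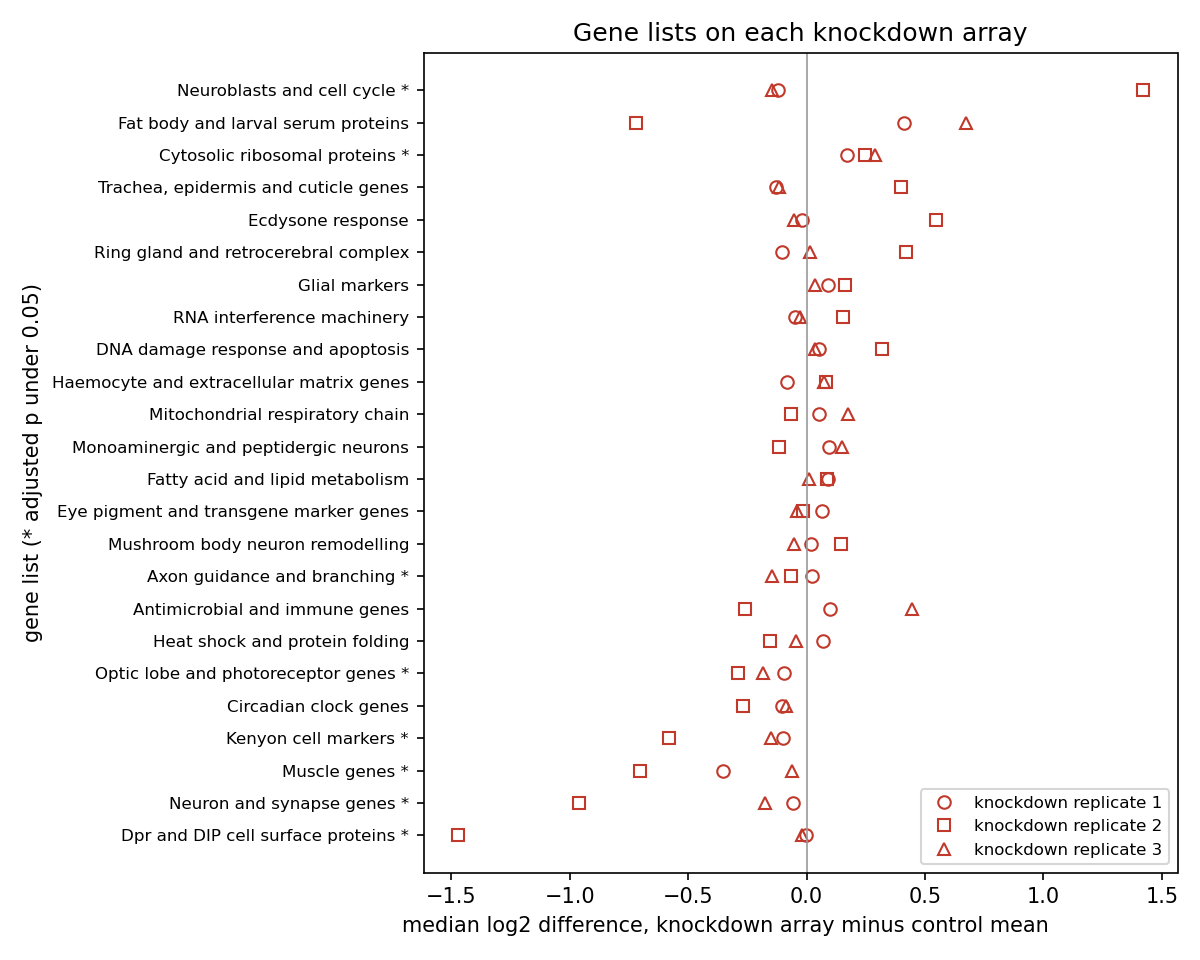
Median log2 difference of the members of each of the 24 gene lists (horizontal axis) on each knockdown array from the control mean, with the lists on the vertical axis. Points are single knockdown arrays and a star marks the 8 lists with an adjusted p under 0.05. Knockdown replicate 2 lies at 1.42 for neuroblast and cell cycle genes and at -1.47 for Dpr and DIP cell surface proteins, where the other knockdown arrays lie close to 0.

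The remaining lists missed the threshold. Circadian clock genes had a median of -0.17 (adjusted p 0.113), with the neuropeptide gene Pdf at 0.65 (SE 0.18). Heat shock and protein folding genes had a median of -0.07 (adjusted p 0.350), with Hsp70Bbb at -0.98 (SE 0.24). RNA interference machinery had a median of 0.09 (adjusted p 0.728), with vig at -0.83 (SE 0.19) and AGO3 at 1.02 (SE 0.29). Ecdysone response genes had a median of 0.18 (adjusted p 0.728), with Eip63E at -0.79 (SE 0.20). DNA damage response and apoptosis genes had a median of 0.07 (adjusted p 0.728), with the Bcl-2 family gene Buffy at 0.53 (SE 0.12). Antimicrobial and immune genes had a median of -0.05 and a mean of -0.06 while camera's direction was up (adjusted p 0.782), with PGRP-LB at 0.73 (SE 0.16) and Tep2 at 0.83 (SE 0.19). Fatty acid and lipid metabolism genes had a median of 0.03 and a mean of -0.01 (adjusted p 0.986), with the acetyl-CoA carboxylase gene ACC at -0.62 (SE 0.20). Monoaminergic and peptidergic neuron genes had a median of 0.06 and a mean of -0.01 (adjusted p 0.967), with the leucokinin gene Lk at 1.45 (SE 0.48). Eye pigment and transgene marker genes had a median of 0.02 while camera's direction was down (adjusted p 0.869). Leaving out a single array moved the median of each of the 16 lists that missed the threshold by over 1.5 times or turned it. The same held for each of the 8 lists past the threshold. Leaving out knockdown replicate 2 gave -0.06 for circadian, -0.0031 for heat shock, -0.01 for RNA interference, -0.04 for ecdysone response, 0.04 for DNA damage, 0.27 for antimicrobial and 0.11 for monoaminergic and peptidergic genes, and Lk was at 0.95. The antimicrobial median was 0.11 without control replicate 2 and 0.0079 without control replicate 3. The eye pigment median was -0.012 without control replicate 1 and -0.019 without knockdown replicate 1, and the monoaminergic and peptidergic median was -0.038 without knockdown replicate 3. The lipid median was 0.058, 0.060 and 0.047 without control replicates 1, 2 and 3 and 0.070 and 0.060 without knockdown replicates 1 and 3. Heat shock genes passed after quantile normalisation (median -0.12, adjusted p 0.0192), in the authors' value table (median -0.13, adjusted p 0.0121) and with the repaired normexp correction (median -0.08, adjusted p 0.0470), and circadian genes passed with every probe tested (median -0.14, adjusted p 0.0430).

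The lists of glial, fat body, haemocyte, ring gland, trachea and mitochondrial genes also missed the threshold with all 6 arrays. Medians were 0.12 for glial markers (adjusted p 0.579), 0.22 for fat body and larval serum proteins (adjusted p 0.728), 0.07 for haemocyte and extracellular matrix genes (adjusted p 0.986), 0.14 for the ring gland and retrocerebral complex (adjusted p 0.782), 0.21 for trachea, epidermis and cuticle genes (adjusted p 0.728) and 0.06 for the mitochondrial respiratory chain (adjusted p 0.728). Leaving out knockdown replicate 2 gave medians of 0.53 for fat body (adjusted p 0.060), -0.01 for haemocyte, -0.0059 for ring gland and -0.10 for trachea genes. The fat body median was 1.22 on slide 1, -0.11 within slide 2 and -0.0022 without control replicate 1. Without control replicate 1 the medians of haemocyte and mitochondrial genes were -0.00076 and -0.0084, without control replicate 3 that of ring gland genes was -0.03, and without knockdown replicate 1 that of glial markers was 0.06. In the authors' value table the mitochondrial genes were lower (median -0.10, adjusted p 0.0297). In the lists that missed the threshold, 0 members passed adjusted over the list alone with all 6 arrays. Without knockdown replicate 2, 1 member did so in each of the antimicrobial, DNA damage and monoaminergic and peptidergic lists. A further 3 lists had too few measured members for a test. Gut and salivary gland genes had a median of -0.06 over 3 members, and yolk protein and female genes had a median of -0.06 over 4 members. Of 4 measured male-specific transcripts, the dosage compensation RNAs roX1 and roX2 and their partner gene msl-2 were higher on all 3 knockdown arrays than on any control array, by 1.14 (SE 0.39), 1.42 (SE 0.56) and 0.32 (SE 0.12). The remaining member was below 0. Of the 4 transcripts, 0 passed adjusted over the list alone (smallest adjusted p 0.0574). Without knockdown replicate 2 their median was 0.75, and 1 of them passed adjusted over the list alone.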

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

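The test of probes without a gene name was chosen only after the data were examined. Of 5074 such probes above background, which the comparison of genes does not use, 12 passed an adjusted p of 0.05 in a limma fit to all kept probes, 8 higher and 4 lower in knockdown, and 401 had an unadjusted p under 0.05. Without knockdown replicate 2, 30 passed. Several were detected in 1 group alone. A probe at 21569054 to 21569113 on 3L was at least 40.6-fold lower in knockdown (adjusted p 6.03e-05), and a probe at 22746060 to 22746119 on 3L was at least 8.99-fold lower (adjusted p 0.000269). A pair of overlapping probes on 3R, starting at 10508664 and 10508673, was at least 13.2-fold and 11.7-fold lower. A probe that starts at 1329085 on chromosome 4 was at least 38.4-fold higher (adjusted p 0.00223), and a probe that starts at 8939857 on 2L was at least 13.6-fold higher (adjusted p 0.00593). No explanation was tested for these probes.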

How the results depend on the processing

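The fit to slide 2 alone and the repaired normexp correction were chosen only after the data were seen. The direction of gkt held under all 21 alternatives, at -1.93 to -1.49, and it passed the threshold with array weights (-1.49) and without knockdown replicate 2 (leaving out single arrays gave -1.74 to -1.52), with adjusted p values of 0.000818 to 0.930 over all of them. The level of DIP2 reversed within slide 2 (0.012) and without control replicate 1 (leaving out single arrays gave -0.26 to 0.0092), with adjusted p values of 0.577 to 1.00. Where no cause is named for a change, the cause was not tested.

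The count of 4 genes was 0 with normexp (71 genes at unadjusted p under 0.05 in limma), with its repaired form (332), with probes well above background on all arrays (442), with a trended robust prior (484), with the authors' value table (532), with the replicate block (436), with the slide block (489) and on slide 2 alone (228). It was 1 without a filter, 2 with quantile normalisation, 11 with every probe tested and 272 with array weights, which gave knockdown replicate 2 a weight of 0.0847 and control replicate 2 a weight of 8.79. Leaving out single arrays gave 0 to 43, the highest without knockdown replicate 2. The calls split into 0 higher and 2 lower with quantile normalisation, and into 2 higher and 3 lower with the 75th percentile of detected probes. In each of the 4 called genes the adjusted p lay between 0.000591 and at least 0.814 over the alternatives. P5CDh2 passed in 9 of 19 alternatives, TTLL15 in 8 of 19, CheB53a in 6 of 19 and CG11052 in 6 of 20. The 110 genes with a 2-fold change became 25 with normexp, 29 with its repaired form, 185 without a filter, 64 with probes well above background on all arrays and 6 with the authors' value table, and leaving out single arrays gave 80 to 185 (185 without knockdown replicate 1, 179 without knockdown replicate 3). The 8 lists became 5 with array weights, 0 with an estimated correlation and 0 with fry, whose smallest adjusted p values were 0.710 and 0.483. Between arrays of the same number, deviations from the group mean had correlations of 0.06, -0.06 and -0.08 across genes. The knockdown mean includes replicate 2, which stands apart, so these values cannot show whether the replicate numbers pair the arrays. Replicate 1 of both groups shared a slide.

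The normexp fit failed on some arrays by its construction. In knockdown replicate 2, 4 spots lay below their local background, by up to -338522, and raised the fitted noise to 2873 from 0.623 without them. It is therefore given for the counts, gkt and DIP2 only. The repaired form leaves these spots out, but its offset of 50 still compresses dim genes.

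Among the other named genes, 3536 results under an alternative kept their direction and side of the threshold, 44 passed it newly, 48 lost it and 34 reversed. All 48 losses were in the 4 called genes. CG11052 lost the call in 14 of 20 alternatives, CheB53a in 13 of 19, TTLL15 in 11 of 19 and P5CDh2 in 10 of 19. The other genes missed the threshold with all 6 arrays and had no call to lose, so the 3536 kept results do not show that calls were stable. All genes that reversed had adjusted p values of 0.0291 to 1.00 over their alternatives. With the repaired normexp, PGRP-SC2 reversed to 0.11, Clk to 0.18, Blm to 0.0075, DIP-eta to 0.028, Amy-p to 0.26, WDY to 0.24, fln to 0.069 and up to 0.15. With the mean of a gene's probes, RpS21 reversed to 0.17 and dpr9 to 0.0090. With the authors' value table, RpL5 reversed to -0.035, RpL8 to -0.032, RpL36A to -0.12 and RpS7 to -0.038, and with quantile normalisation sta to -0.020 and RpL36A to -0.021. With array weights, CycE reversed to -0.0019, BubR1 to -0.096, grh to -0.057, Jheh2 to -0.020 and Npc1a to -0.19. On slide 2 alone LManII reversed to 0.046. Leaving out single arrays gave -0.13 to 0.042 for LManII (reversed without knockdown replicate 1), -0.73 to 0.59 for WDY (without control replicate 2 or knockdown replicate 3) and -0.038 to 0.13 for fl(2)d (without control replicate 2). Without knockdown replicate 2 more genes reversed, and the ranges over single arrays were -0.057 to 2.01 for wor, -0.038 to 1.21 for CycE, -0.064 to 2.09 for ase, -0.0093 to 0.83 for BubR1, -0.086 to 1.07 for grh, -0.028 to 1.18 for Jheh2, -3.36 to 0.13 for Jhe and -0.029 to 0.84 for Npc1a. On an array 62.4% to 66.9% of spots were well above background. Whether signal over background accounts for any of these reversals was not tested.

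Among lists, 456 results kept the sign of the median and the side of the threshold, 4 passed newly, 25 lost the call and 43 had a median of the other sign. All 25 losses were in the 8 lists past the threshold, since the other lists had no call to lose. Of the lists past the threshold, neuroblast and cell cycle genes turned to -0.060 with array weights and ribosomal proteins to -0.022 with quantile normalisation and -0.048 with the authors' value table. Leaving out single arrays gave -0.13 (without knockdown replicate 2) to 0.62 for neuroblast and cell cycle genes, and slide 2 alone gave 0.63. The other lists that turned missed the threshold with all 6 arrays. With array weights, trachea genes turned to -0.13, ring gland to -0.20, ecdysone response to -0.0068, heat shock to 0.017, RNA interference to -0.052 and haemocyte genes to -0.15. Antimicrobial genes turned to 0.0054 with the authors' value table, 0.079 with every probe tested, 0.18 without a filter, 0.14 with probes well above background on all arrays and 0.20 with the repaired normexp, and mitochondrial genes to -0.097 with the authors' value table, where they passed the threshold, -0.064 with quantile normalisation and -0.033 on slide 2 alone. Eye pigment genes turned to -0.028 with every probe tested, -0.023 with the mean of a gene's probes, -0.010 with median scaling and -0.038 on slide 2 alone. Mushroom body remodelling genes turned to -0.027 with median scaling and -0.0049 with quantile normalisation, lipid genes to -0.0018 with median scaling, and fat body genes to -0.11 and monoaminergic and peptidergic genes to -0.00040 on slide 2 alone. Leaving out single arrays gave -0.23 to 0.27 for antimicrobial, -0.042 to 0.36 for ecdysone response, -0.019 to 0.074 for eye pigment, -0.0022 to 0.53 for fat body, -0.011 to 0.11 for haemocyte, -0.0084 to 0.088 for mitochondrial, -0.038 to 0.11 for monoaminergic and peptidergic, -0.0080 to 0.084 for mushroom body remodelling, -0.028 to 0.32 for ring gland, -0.013 to 0.13 for RNA interference and -0.097 to 0.36 for trachea genes. The lists that missed the threshold and kept their sign without single arrays gave -0.24 to -0.062 for circadian, 0.025 to 0.098 for DNA damage, 0.041 to 0.070 for lipid, 0.057 to 0.14 for glial and -0.098 to -0.0031 for heat shock genes. Among the called lists that kept their call, the authors' value table gave -0.26 for neuron and synapse genes, -0.13 for Kenyon cell markers, -0.18 for Dpr and DIP proteins, -0.044 for optic lobe and photoreceptor genes, -0.091 for muscle genes and 0.20 for neuroblast and cell cycle genes. Array weights gave -0.11 for neuron and synapse genes and -0.12 for Kenyon cell markers, and the repaired normexp -0.13 for muscle genes. Every probe tested gave -0.15 and the mean of a gene's probes -0.17 for Kenyon cell markers. Axon guidance genes were at -0.081 with every probe tested, -0.085 with the mean of a gene's probes, -0.084 with quantile normalisation and -0.071 with median scaling. Over all alternatives the adjusted p was 0.060 to 0.967 for fat body genes and 0.00291 to 0.710 for optic lobe and photoreceptor genes.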

Other observations

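The counts over other splits of the arrays were fixed before the data were examined, except that of genes at an unadjusted p under 0.05, which like the tests of knockdown replicate 2 and of the genes called without it was chosen only after those results were seen. Knockdown replicate 2 held a different balance of cell and tissue transcripts from the other knockdown arrays. The neuroblast genes dpn, mira, ase and wor were higher on it by 3.86, 3.53, 4.09 and 4.13 on the log2 scale, and the cell cycle gene CycE by 2.496. The neuronal RNA-binding protein gene Rbp9 was lower by a difference of -4.71, while the pan-neuronal gene elav differed by 0.10. The chitin deacetylase gene serp was higher by 6.97 and the ecdysteroid synthesis gene sro by 6.09, and the antimicrobial peptide gene Drs differed by -6.34 and rdhB, a retinoid dehydrogenase gene, by -10.49. In all, 712 genes were at least 2-fold higher and 1089 at least 2-fold lower on this array than the mean of the other knockdown arrays, where knockdown replicates 1 and 3 differed by that much in 51 and 89 genes. dpn, mira, Rbp9, elav, serp, sro, Drs and rdhB were chosen after their values were seen.

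Knockdown replicate 2 stands apart from the other 5 arrays, with a deviation that was shared between 2 probes of the same gene with a correlation of 0.867 across 3453 genes, which argues against noise of single spots or an uneven hybridisation. Of the 43 genes that differ without it, 34 had it beyond every control array on the side of the other knockdown arrays. It lay beyond the control range on the other side for 4, and within it for 5, Fmo-2 and mthl3 among them. A control array of usual spread would by chance lie beyond on a given side in 25% of genes and seldom in more than 17. That bound treats genes as independent, and it does not hold for an array that deviates more. Knockdown replicate 2 did so, with an SD of deviations across genes of 1.08 against 0.29 to 0.41 in control arrays. The count of 34 against 4 still argues against a swap with a control. A looser count tried first, of genes in which this array lay nearer to the other knockdown arrays, gave 26 of 43 and did not decide. The median of the neuroblast and cell cycle list lay at the 100th percentile of 10000 random lists matched for level and that of the neuron and synapse list at the 0th (medians 1.55 and -0.92), while fat body and larval serum protein genes shifted more, by -2.16 (0th percentile), muscle genes by -0.53 (0.345th percentile) and ring gland genes by 0.55 (99.8th percentile). Ecdysone response genes shifted by 0.61 (100th percentile) and Dpr and DIP cell surface proteins by -1.46 (0th percentile). Tissue from an earlier developmental stage and a different share of tissues in the dissection cannot be told apart. These lists had been seen to differ on this array, and no separate measure of the stage was made.

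Genes on 2L, 2R, 3L, 3R and 4 made up the 43 that differ between the groups without knockdown replicate 2, and 39 of these differed at least 2-fold. gkt at 3163088 and CG31955 at 3712220 on 2L were lower, by differences of -1.52 and -2.13, and ninaA, the rhodopsin chaperone gene, by -1.70. sob at 3578070, between gkt and CG31955, was lower too and was detected on all 3 control arrays but on 0 of the 2 knockdown arrays compared. mthl4 and mthl3, whose probes start 3170 bases apart, changed in opposite directions. Higher genes included the synaptotagmin gene Syt7 with 1.53 and Pfk, the phosphofructokinase gene of glycolysis, with 1.19. sob, ninaA, Syt7 and Pfk were chosen after their values were seen.

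Of these 43 genes, 17 had another kept probe. In 11 of them (64.7%) another probe moved the same way at an unadjusted limma p under 0.05. For the genes with another probe, this argues against a sequence difference under single probes as the whole cause. Probes of a gene can lie close together, as in Dnaaf3 and P5CDh2, so wider sequence differences were not tested. 0 of the 43 lay on X, where 7.11 would match its share of 16.5% among the genes tested (Fisher exact p 0.000677), and differences in the genetic background of the fly lines on the autosomes may contribute. A test tried before that one gave 6 genes within 50 kb of another, against a median of 2 in random sets (94.6th percentile), and did not decide. The rule for naming the background required both tests to pass, so the question stayed undecided. The background and a knockdown of DIP2 cannot be told apart, because every knockdown array carries the RNAi transgene and no control does. The DIP2 difference of -0.15 over overlapping groups does not decide it. The RNA came from the whole central brain, so that level cannot show whether DIP2 fell in the mushroom body cells of the driver.

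The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. As many genes past the adjusted threshold came from 1 split, the real one with 4, and the highest other count was 0. As many genes with a 2-fold change and an unadjusted p under 0.05 came from 1 split, the real one with 110, and the highest other count was 72. As many genes at an unadjusted p under 0.05 alone came from 2 splits, the real one with 486 and the split of control replicates 1 and 2 with knockdown replicate 2 from the rest, with 590. For gene lists, 5 splits, the real one included, gave at least the real count of 8, and the highest other count was 9. The splits other than the real one gave 5 to 9 lists each.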
